A study of Mus musculus with 95 samples.

How the data were processed

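The series holds 95 mouse brain samples, each one a 384-well plate of single cells sequenced with MARS-seq2.0, a 3′ end method with unique molecular identifiers (UMIs) in which each well receives 1 sorted cell. Wild-type (WT) mice and 5xFAD mice, a transgenic line that deposits amyloid, were compared at several ages. The genotype was read from the strain label, which is B6.SJL for the mice called WT here and 5xFAD for the others. In all, 47 plates hold CD45- (non-immune) cells and 48 plates hold cells positive for galactocerebroside (GalC+), a lipid of the oligodendrocyte surface. Per the labels' protocols, brains were digested with papain, debris was removed on a density gradient, dead cells and doublets were gated out, and the gates enriched for GalC or Ly6A/E in some sorts, so that the share of a cell class on a plate is set by the sort. The labels also describe 4 wells without a cell on each plate, which the tables do not mark and which were not used here.

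The deposited tables hold raw UMI counts per gene and well, with no normalization. Reads were converted with bcl2fastq 2.20.0.422 and the build was mm10, per the submitters' processing notes. The aligner, the UMI collapsing and the gene annotation are not given in the sources used here. A deposited table lists the sequencing batch of each well, and has no rows for 1 plate. Gene coordinates are those of GENCODE vM21 on mm10 and were found for 285 of the 287 named genes. How the authors' counting treated reads shared by near-identical genes (H2-D1 and H2-K1, C4b and C4a, the haemoglobin genes) is not known, so values of these genes are uncertain.

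Of 36480 wells, 20352 were kept as cells: 14145 held under 500 UMIs, 1 held over 20000, and 1982 held more than 30% mitochondrially encoded UMIs. No doublet caller was run, because each well received a sorted single cell. The plates hold 35459442 UMIs in all, between 168562 and 561289 per plate (median 378484), with 62 to 315 kept cells per plate and a median of 715 to 2190 UMIs per cell. Cells of both sorts were scaled to 1000 UMIs, log transformed and clustered together (scanpy 1.11.5, 2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 with a resolution of 0.1). A higher resolution was tried first and split classes into clusters that the naming rule could not name; the resolution was lowered after those clusters were seen. A cluster was called X-like from markers fixed before the data were examined. A cluster of 493 cells led by myeloid genes (Lyz2, Ccl4, Ctss) that also carried oligodendrocyte transcripts stayed unnamed and entered no comparison.

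UMI counts were summed per plate and class, for plates with at least 10 cells of the class. Each sum was tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, the quasi-likelihood test, and Benjamini-Hochberg adjustment with a threshold of 0.05. One model per sort and class held a term for each group (genotype and age) and a term for the plate series, which is given by the leading digits of the plate name. Standard errors were computed as the log2 fold change divided by the square root of the F statistic. A series term that could not be told from a group was left out. This applies to series 87 in the 10-month GalC+ comparison and to 11 months in CD45- astrocyte-like cells, where the values hold the difference between series too. Counts of plates above or below a WT mean use the mean of all WT plates compared, except where the mean of the same series and age is named. In the CD45- sort the genotype effect is the unweighted mean over the ages with plates of both genotypes. The replicate is the plate, since the deposited tables name no animals. Plates of 1 group can come from the same animal: pairs of plates of 1 group, series and sex differed less (152 pairs, median chi-square per degree of freedom 2.36) than pairs of 1 group from other series or of the other sex (189 pairs, 5.16). P-values over plates are then too small as statements about animals. Each comparison was therefore also run with plates summed into the 26 sets of 1 series, group and sex, chosen after the data were seen. The count of calls is given beside each result that keeps more than 1 set in each arm. In the CD45- sort the summed fit used another model. It kept only series and ages with sets of both genotypes, and fitted 1 genotype effect, or its trend with age, within those pairs. Its folds there are not the unweighted means over ages, so they can differ from the folds over plates for that reason too. Summing leaves 1 5xFAD set at 15 months and 1 WT set at 10 months in the GalC+ sort. The spread in those fits comes from other groups, so for both ages and for genotype by age folds alone are given. Plates hold different cells, so the tables cannot show which plates share an animal. Sex was read from Xist and Y-linked UMIs: 39 plates are female and 56 male.

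Gene lists were fixed before the data were examined and tested with limma 3.58.1 (camera with a correlation of 0.01, at least 5 tested members); the adjusted p with an estimated correlation is given where it ends a call. A list member counts as risen or fallen when its own adjusted p passes over all genes tested; counts adjusted over the list alone are given beside. The disease-associated oligodendrocyte list may hold genes that the study chose on these samples, so its direction is not independent evidence, and counts adjusted over this list alone are not independent evidence either. The genes named in each comparison are the 10 largest rises and 10 largest falls among called genes with a mean of at least 20 CPM (predicted gene models and ribosomal protein genes left out), all tested members of the list most relevant to the class, up to 4 members of each other list, and App. The result for a further gene is not reported here. Other genes were chosen after their values were seen, and are said to be.

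The share of cells with a Serpina3n UMI was taken per plate after each cell was thinned to 500 UMIs, and tested by permutation of genotype labels within plate series, two-sided. Intervals of shares are 95% Wilson intervals and cover counting error only. A gene with no UMI in 1 arm is given as a bound against a floor of 3 UMIs over that arm.

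The test was checked on simulated counts with 100 genes changed by each fold. The simulated plates were independent and held no difference between series, sexes or animals. The rates below therefore do not cover plates that share an animal. For the trend with age the stated fold was reached within a part of the range of ages, so the change over the whole range was larger. At 2-fold and 4-fold it recovered 74% and 94% in the 24-month GalC+ comparison, 40% and 85% at 15 months, 46% and 83% at 10 months, 31% and 79% for genotype by age, 69% and 94% for WT age, 74% and 89% in CD45- oligodendrocyte-like cells, 43% and 89% for their trend with age, 90% and 95% in astrocyte-like cells, 87% and 86% in endothelial-like cells, and 21% and 71% in mural-like cells. Of the calls 3.6% to 9.9% were unchanged genes: 9.9% in CD45- oligodendrocyte-like cells, 7.6% for genotype by age, 7% in endothelial-like cells, and at most 5.1% in the others. Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, at least 1000 UMIs per cell, no mitochondrial limit, no series term, at least 30 cells per plate, all kept cells of the GalC+ sort, and leaving out plates. Alternatives by sex, by set of plates, without series 91, without the 11-month plates and with the unnamed cluster added were chosen after seeing the data.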

Results

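Single-cell transcript counts were collected from whole brains of WT and 5xFAD mice to compare non-immune cells, and oligodendrocytes in particular, between genotypes and ages. The CD45- sort holds 47 plates: 6 WT and 8 5xFAD plates at 6 months, 3 and 3 at 8 months, 3 and 3 at 10 months, 5 and 7 at 11 months, and 3 and 6 at 15 months. The GalC+ sort holds 48 plates: 2 WT and 9 5xFAD plates at 10 months, 6 and 3 at 15 months, and 14 and 14 at 24 months. Total depth was 194944 to 551937 UMIs per CD45- plate and 168562 to 561289 per GalC+ plate. The labels name no animals, so p-values measure the spread between plates, which may be technical or come from plates that share an animal.

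Oligodendrocyte-like cells made up 79.3% of the kept GalC+ cells (8335 of 10508), followed by 7.1% astrocyte-like and 6.5% endothelial-like cells. In the CD45- sort, 33.7% of cells were oligodendrocyte-like (3317 of 9844), 25.6% endothelial-like (2520 cells), 22.6% astrocyte-like (2226 cells), 4.2% choroid plexus-like, 4.0% mural-like, 3.0% olfactory ensheathing-like, 2.5% neuroblast-like, 2.0% erythrocyte-like, 1.6% fibroblast-like and 0.6% ependymal-like. These shares are set by the sort, so differences in them between groups are not tested and are given below as background alone. No cluster was named microglia-like or precursor-like.

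At 24 months, GalC+ oligodendrocyte-like cells of 5xFAD mice held more transcripts of a secreted protease inhibitor, a complement component and the antigen-presenting MHC class I molecule than those of WT mice. Serpina3n, which encodes a serine protease inhibitor (mm10, chromosome 12, 104406729 to 104414329), rose by a log2 fold change of 2.48 ± 0.26 (SE, 14 against 14 plates in the fit, adjusted p = 5.65e-11) and lay above the WT mean in 14 of 14 plates. The 7 5xFAD plates of series 91, which holds no WT plate, are included in these counts of plates. Their series term takes them up, so they add nothing to the folds. The class I heavy chain gene H2-D1 (chromosome 17, 35262730 to 35267499) rose by 1.25 ± 0.19 (14 of 14 plates), its light chain B2m (chromosome 2, 122147686 to 122153083) by 1.06 ± 0.16 (14 of 14) and H2-K1 by 1.12 ± 0.28 (13 of 14). C4b, complement component 4 (chromosome 17, 34728380 to 34743882), rose by 1.22 ± 0.21 (11 of 14 plates), and Fxyd1, a regulator of the sodium pump, by 2.66 ± 0.37 (13 of 14). Of the 14 tested members of the disease-associated oligodendrocyte list, 6 rose, none fell and 8 did not pass (7 rose when adjusted over the list alone). The list median was 0.44 and the list was called (adjusted p = 3.61e-14). The tetraspanin gene Cd9 was the 6th riser, by 0.56 ± 0.12, while Il33 (0.25 ± 0.14), Klk6 (0.16 ± 0.24) and Cd63 (0.43 ± 0.13, adjusted p = 0.0696) did not pass.

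Other genes that rose at 24 months were Gadd45a, a stress-induced gene (1.60 ± 0.31), the transcription factor gene Cebpd (1.48 ± 0.34), Clptm1 (1.33 ± 0.36), Rasal1 (1.22 ± 0.29), the myelin gene Opalin (0.49 ± 0.11) and the lysosomal gene Psap (0.47 ± 0.11). Among the falls were Stmn1, which encodes a microtubule regulator (-2.04 ± 0.32), Efr3b (-1.57 ± 0.35), Dusp26 (-1.41 ± 0.36), Tceal3 (-1.36 ± 0.33) and Rapgef5 (-1.27 ± 0.28, below the WT mean in 14 of 14 plates). Transcripts typical of other tissues moved as well. Ttr, the transthyretin gene of the choroid plexus, had 0 UMIs in the 7 5xFAD plates of the series that hold both genotypes and 548 in the WT plates, at least 145-fold lower. Choroid plexus-like cells were 34 of 2237 WT and 1 of 3182 5xFAD cells of the sort at that age, and 18 of 1353 WT and 0 of 669 5xFAD cells at 15 months. The haemoglobin genes Hbb-bs (-5.07 ± 1.38) and Hba-a1 (-4.05 ± 1.12) also fell. Their direction was not stable: Hbb-bs was 0.61 in males alone and Hba-a1 0.03 with at least 1000 UMIs per cell. The Y-linked gene Ddx3y was called (1.94 ± 0.53) because the sexes are not balanced within series. Endogenous App (-0.02 ± 0.09) did not pass. The transgenes are human sequences, so this value does not check the labels.

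In all, 97 of 6413 genes were called at 24 months by edgeR's quasi-likelihood test, 55 higher and 42 lower in 5xFAD. MHC class I presentation genes were called as a group (3 of 6 rose, also adjusted over the list alone, median 0.77, adjusted p = 1.1e-08). So were the disease-associated astrocyte genes (3 of 10 rose, 5 adjusted over the list alone, adjusted p = 1.1e-08), a list that shares Serpina3n, C4b, Vim, Cd9 and Cd63 with the oligodendrocyte list. Cholesterol synthesis genes were called lower although none of the 15 passed alone (0 fell over all genes, 2 adjusted over the list alone, median -0.36, adjusted p = 0.00136). This list had adjusted p = 0.094 with an estimated correlation. Nuclear genes of oxidative phosphorylation were called higher with none of 25 passing (median 0.13, adjusted p = 0.0113). That call ended (adjusted p = 0.517 with an estimated correlation). Myelin genes were not called as a group (2 of 18 rose, 3 adjusted over the list alone, median 0.02, adjusted p = 0.592), nor were lysosome genes (1 of 18 rose, 2 adjusted over the list alone, adjusted p = 0.131). The genotype contrast rests on the series with both genotypes, which hold 5xFAD males and WT plates of both sexes. With a sex term 55 of the 97 genes were called again and 2 changed sign, and with males alone at 24 months 35 were called again and 4 changed sign. In males alone Serpina3n (1.86, adjusted p = 0.00147), C4b (1.80, 0.000119) and B2m (0.97, 0.0177) passed, and H2-D1 (0.71, 0.272) and Fxyd1 (1.60, 0.17) did not. With plates summed by series, group and sex, 9 genes were called, 7 of the 97 among them. Serpina3n (2.47, adjusted p = 0.00288), H2-D1 (1.23, 0.0415), B2m (1.06, 0.0415), Fxyd1 (2.70, 0.0344), Clptm1 and Ttr were called again among the named genes, and C4b (1.23, adjusted p = 0.932) and H2-K1 (1.13, 0.479) were not.

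The rise of Serpina3n was also seen as a share of cells. Within the plate series that hold both genotypes at 24 months, 10.2% ± 2.43 of 5xFAD oligodendrocyte-like cells (SD, n = 7 plates) and 2.61% ± 1.90 of WT cells (n = 11) held a Serpina3n UMI at 500 UMIs per cell, a difference of 7.62 percentage points (exact permutation p = 0.000101 within series, the smallest that 9900 permutations can give). Of the 7 5xFAD plates 7 lay above the highest WT plate, 5 at 1000 UMIs per cell and 2 without thinning. Without thinning the shares were 23.1% and 10.5%. At 15 months, 32.0% ± 4.09 of 5xFAD cells (n = 3) and 1.25% ± 0.84 of WT cells (n = 3) of the same series held one. With 3 against 3 plates an exact two-sided p cannot go below 0.1, which is the value found. Over both series of that age, with labels not held within series, the WT share was 1.12% ± 0.80 (n = 6) and p was 0.0119. As background, 0.22% of 5xFAD and 0.18% of WT endothelial-like CD45- cells held a Serpina3n UMI, at median depths of 1072 and 1100 UMIs, against 6.35% and 0.73% of the CD45- oligodendrocyte-like cells at 1401 and 1460. In the GalC+ sort 2.60% of 577 5xFAD endothelial-like cells held one (95% interval 1.58 to 4.24) and none of the WT cells (0 to 3.66). Astrocyte-like cells held one at 5.83% in 5xFAD and 0.60% in WT in the GalC+ sort, and at 2.37% and 0.80% in the CD45- sort. Olfactory ensheathing-like CD45- cells held one at 15.1% and 15.9%.

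**Figure D1:**
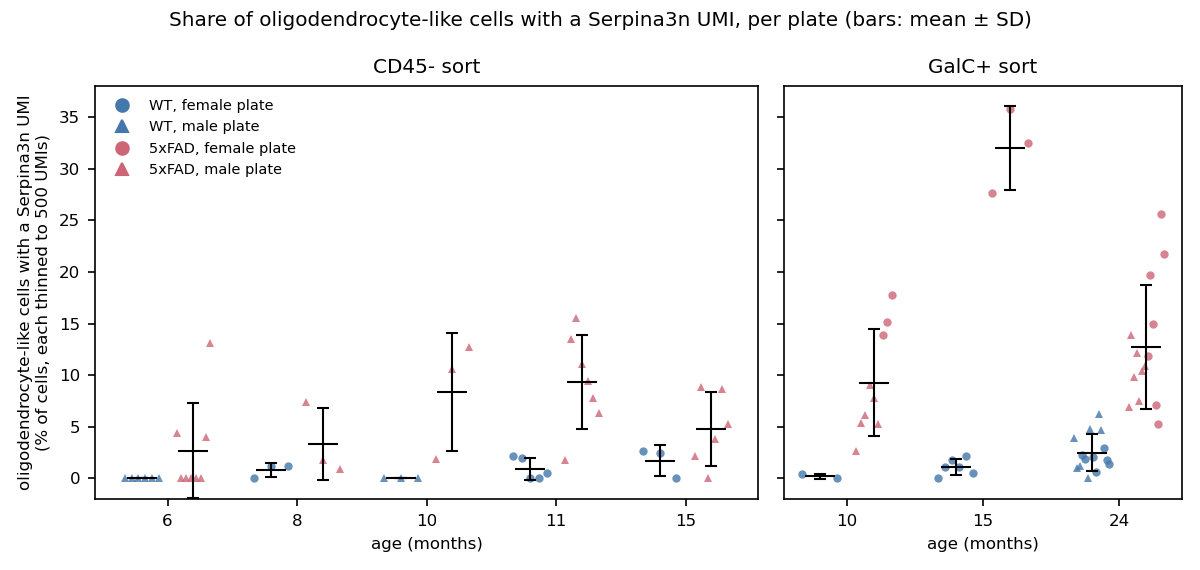
Share of oligodendrocyte-like cells with at least 1 Serpina3n UMI (%, each cell thinned to 500 UMIs) per plate, by age in months, for the CD45- sort (left) and the GalC+ sort (right); circles are female and triangles male plates, blue WT and red 5xFAD, and bars are the mean ± SD of all plates of a group. The 3 5xFAD plates at 15 months lie between 27.7% and 35.8%, and the 14 WT plates at 24 months between 0% and 6.25%.

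At 15 months many of the same genes were called. Serpina3n rose by 5.84 ± 0.42 (3 5xFAD against 6 WT plates, adjusted p = 4.28e-18), Fxyd1 by 4.55 ± 0.56, Klk6, a secreted kallikrein protease (chromosome 7, 43824499 to 43832030), by 3.33 ± 0.39, C4b by 3.12 ± 0.42 and H2-D1 by 2.63 ± 0.28. B2m rose by 2.00 ± 0.26 and H2-K1 by 1.92 ± 0.45. Higher as well were Vim, an intermediate filament gene (2.86 ± 0.53), the growth factor receptor-like gene Fgfrl1 (2.83 ± 0.50), Aldh1l2, a mitochondrial folate enzyme (2.65 ± 0.41), Hopx (2.16 ± 0.28) and Cela1 (2.06 ± 0.39), each in 3 of 3 plates. Sgk1, a glucocorticoid-induced kinase (chromosome 10, 21882184 to 21999903), fell by 3.25 ± 0.40 on the log2 scale. Also lower were Arl4d (-3.59 ± 0.46), Ddit4, a stress-induced inhibitor of mTOR signalling (-2.38 ± 0.55), the NF-κB inhibitor gene Nfkbia (-1.74 ± 0.28), Syne1 (-1.72 ± 0.44) and Amer2 (-1.51 ± 0.27).

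At this age 9 of 14 members of the disease-associated oligodendrocyte list rose and 1, Sgk1, fell (10 and 1 adjusted over the list alone, median 1.48, adjusted p = 5.44e-27). Il33, an alarmin cytokine, rose by 0.85 ± 0.20 and Cd63 by 1.05 ± 0.19. MHC class I genes rose in 3 of 6 members (4 adjusted over the list alone, median 1.51, adjusted p = 2.09e-12). Lysosome genes were called higher with 3 of 18 rising (5 adjusted over the list alone, adjusted p = 0.000122), among them Ctsb, cathepsin B, by 0.75 ± 0.15 and Psap by 0.58 ± 0.17. Genes of the unfolded protein and integrated stress response were called higher with none of 12 passing alone (3 adjusted over the list alone, median 0.33, adjusted p = 0.00117). Interferon response genes were called with 1 of 7 rising, Ifi27 (0.87 ± 0.21; 2 adjusted over the list alone, adjusted p = 0.0443), but adjusted p = 0.115 with an estimated correlation. Oligodendrocyte markers rose in 2 of 12, Trf, transferrin (0.85 ± 0.14), and Cldn11 (0.54 ± 0.14; 2 adjusted over the list alone, adjusted p = 0.00586), and adjusted p = 0.342 with an estimated correlation. Astrocyte-like cells were 180 of 1353 WT and 32 of 669 5xFAD cells of the sort at this age. The astrocyte marker list was lower in the oligodendrocyte-like cells of the same plates. Its median was -0.60 over 7 members (1 fell, Gja1 or connexin 43, with 1 UMI in the 3 5xFAD plates; 3 adjusted over the list alone, adjusted p = 0.00256, and adjusted p = 0.119 with an estimated correlation). Sparcl1, outside that list, fell by 2.17 ± 0.54 and Ttr by 4.97 ± 1.03. The ciliary gene Foxj1 (2.34 ± 0.57) and the neuronal genes Tubb3 (1.99 ± 0.47) and Olfm1 (1.03 ± 0.26) rose.

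The 15-month comparison called 143 of 6413 genes by edgeR's quasi-likelihood test, 93 higher and 50 lower. All 15-month plates are female. Of the genes higher at 15 months, 21 were also higher at 24 months (0.80 expected of independent lists), and 5 genes were lower at both ages (0.33 expected). The comparisons use other plates but share series terms. With plates summed by series, group and sex, the 5xFAD arm is 1 set, so that fit cannot measure the spread between 15-month 5xFAD animals. Its folds were close to those over plates: Serpina3n 5.84, H2-D1 2.60, B2m 2.00, Fxyd1 4.64, Klk6 3.26, C4b 3.14, Vim 2.88, Hopx 2.14, Sgk1 -3.25 and Arl4d -3.61. Leaving out 5xFAD replicate 3 left 83 calls.

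At 10 months all 9 GalC+ 5xFAD plates are of 1 series and both WT plates of another, so that genotype and series cannot be told apart and no series term can be estimated. The values below are differences between those 9 plates, 6 of them male, and the 2 WT plates, both female. Serpina3n was higher by 4.92 ± 0.67 (9 of 9 plates, adjusted p = 1.62e-07), C4b by 3.85 ± 0.52, H2-K1 by 2.95 ± 0.58, B2m by 2.21 ± 0.32, H2-D1 by 1.60 ± 0.36, Cd63 by 0.94 ± 0.22 and Cd9 by 0.68 ± 0.19. Fxyd1, at 0 UMIs in WT, was at least 8.08-fold higher and Gbp11 at least 6.99-fold higher. Sgk1 (-3.22 ± 0.32), Arid5b, a chromatin regulator (-2.92 ± 0.22), Dusp26 (-2.90 ± 0.42), Arrdc2 (-2.24 ± 0.26), Arl4d (-1.87 ± 0.31) and Nfkbia (-1.76 ± 0.24) were lower, each in 9 of 9 plates. The myelin genes Mbp (-0.54 ± 0.14) and Mal (-0.62 ± 0.14) and the cholesterol enzyme gene Hmgcs1 (-0.94 ± 0.22) were lower too.

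Markers of other cell types were higher in the same 10-month 5xFAD cells. On these plates endothelial-like cells were 20.6% of kept 5xFAD and 1.56% of kept WT cells, and astrocyte-like cells 325 of 2491 and 38 of 576. Endothelial markers were higher in 9 of 11 members (10 adjusted over the list alone, median 4.80, or 3.44 with genes at 0 UMIs in WT set to their bound; adjusted p = 5.91e-13): Pltp was at least 13.2-fold, Itm2a at least 10.8-fold and the tight junction gene Cldn5 at least 9.02-fold higher. Astrocyte markers were higher in 4 of 7 (7 adjusted over the list alone, median 1.34, adjusted p = 9.32e-06), with Clu, clusterin, by 1.48 ± 0.41. The myeloid gene Tyrobp was at least 3.42-fold higher. Microglia and macrophage markers were called with 1 of 5 higher (2 adjusted over the list alone, adjusted p = 0.0211, and adjusted p = 0.182 with an estimated correlation). Oxidative phosphorylation genes (7 of 25 higher, 15 adjusted over the list alone, adjusted p = 4.26e-10), with Cox7c by 2.08 ± 0.40 and Ndufa4 by 1.91 ± 0.35, and ribosomal protein genes (29 of 109 higher and 5 lower, 50 and 6 adjusted over the list alone, adjusted p = 8.08e-14) were higher as well. The disease-associated oligodendrocyte list had 7 of 14 members higher and 1 lower (9 and 2 adjusted over the list alone, median 1.01, adjusted p = 1.69e-05). In all 407 of 6413 genes were called by edgeR's quasi-likelihood test, 267 higher and 140 lower. With female plates alone there were 654, 343 of the 407 among them, and with no series term in the model 180, 106 higher and 74 lower. Fewer genes were called with WT replicate 1 or 2 left out, or with plates summed by series, group and sex, settings that leave 1 WT sample. In the summed fit the fold was 5.21 for Serpina3n, 3.93 for C4b and -2.97 for Sgk1.

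The difference between genotypes was itself compared between 24 and 15 months. In the series behind this test the 5xFAD plates are all female at 15 months and all male at 24 months, so that age and sex cannot be told apart in 5xFAD. The WT plates take part in the interaction too. Hopx and Klk6 were higher, and Sgk1 and Nfkbia lower, in WT plates at 24 than at 15 months, opposite in sign to their interactions. The difference in Serpina3n was smaller at 24 months by 3.36 ± 0.51 (adjusted p = 1.07e-05), given as an interaction of -3.36. The interaction was also negative for Klk6 (-3.17 ± 0.45), Hopx (-2.31 ± 0.32), Fgfrl1 (-2.59 ± 0.59), Aldh1l2 (-2.19 ± 0.51), C4b (-1.90 ± 0.45), H2-D1 (-1.38 ± 0.33), Ctsb (-0.73 ± 0.17) and Trf (-0.75 ± 0.16). Of these genes Serpina3n, C4b and H2-D1 were called at 24 months, and Hopx lay at -0.15 ± 0.17. The interaction was positive for Arl4d (3.52 ± 0.52), Sgk1 (2.85 ± 0.45), Syne1 (2.35 ± 0.55), Nfkbia (2.19 ± 0.34) and Amer2 (1.25 ± 0.33), which were lower at 15 months and not called at 24 months, where Syne1 (0.63 ± 0.32) and Nfkbia (0.44 ± 0.20) had the opposite sign. Fxyd1 (adjusted p = 0.37), B2m (0.172) and H2-K1 (0.712) had no called interaction. Within plate series 140, mean Serpina3n levels were 1280 ± 65.0 CPM in 5xFAD and 23.7 ± 10.7 CPM in WT females at 15 months (SD, n = 3 and 3). At 24 months they were 313 ± 125 CPM in 5xFAD males (n = 4) and 44.4 ± 9.70 to 84.2 ± 27.8 CPM in WT females and males (n = 4 each). Of the disease-associated oligodendrocyte list 4 of 14 members had a lower and 1 a higher difference at 24 months (8 and 1 adjusted over the list alone, median -0.71, adjusted p = 2.91e-09). The unfolded protein and integrated stress response list was lower with none of 12 passing alone (1 adjusted over the list alone, adjusted p = 0.000189). MHC class I genes were lower in 1 of 6 (3 adjusted over the list alone, adjusted p = 0.00154, and adjusted p = 0.0893 with an estimated correlation). Lysosome genes were lower in 1 of 18 (1 adjusted over the list alone, adjusted p = 0.0154, and adjusted p = 0.0893 with an estimated correlation).

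This test called 43 of 6413 genes by edgeR's quasi-likelihood test, 13 with a higher and 30 with a lower difference at 24 months. The 15-month arm holds 3 5xFAD plates, which become 1 set when summed by series, group and sex, so the summed fit has no replicate there. Its values were 3.54 for Arl4d, 2.79 for Sgk1 and -3.37 for Serpina3n. Leaving out the 3 15-month 5xFAD plates 1 at a time left 22 to 28 calls, the lowest without replicate 1.

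GalC+ oligodendrocyte-like cells of WT plates also differed between 15 and 24 months. The WT 15-month plates are the same as in the 15-month genotype comparison and in genotype by age, so these results are not independent. Against those plates Hopx and Klk6 were higher, and Sgk1 and Nfkbia lower, both in 15-month 5xFAD and in 24-month WT plates. A shift of the WT 15-month plates alone cannot be told from a change with age. In WT plates Hopx (chromosome 5, 77086988 to 77115121) rose by 2.21 ± 0.23 (14 of 14 plates, adjusted p = 1.09e-10) and Klk6 by 2.04 ± 0.33 (14 of 14). Dusp26 rose by 2.16 ± 0.36 (12 of 14), the ubiquitin hydrolase gene Uchl1 by 2.15 ± 0.42 (14 of 14), Stmn1 by 1.91 ± 0.33, C4b by 1.54 ± 0.35 (11 of 14), the annexin gene Anxa5 by 1.23 ± 0.29 and B2m by 0.88 ± 0.21. Serpina3n was higher by 1.50 ± 0.45 and did not pass (adjusted p = 0.0546). Sgk1 (-1.85 ± 0.24), Nfkbia (-1.78 ± 0.20), Kcnab1, a potassium channel subunit (-1.69 ± 0.37), Arrdc2 (-1.65 ± 0.24), Ddit4 (-1.57 ± 0.30) and Arid5b (-1.55 ± 0.17) fell, each in 14 of 14 plates. The myelin genes Opalin (-0.44 ± 0.12) and Tspan2 (-0.43 ± 0.10) fell and Gjb1 (0.43 ± 0.12) rose.

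The disease-associated oligodendrocyte list was not called with age in WT (4 rose and 2 fell of 14, 6 and 3 adjusted over the list alone, adjusted p = 0.0856). MHC class I genes (1 of 6 rose, 2 adjusted over the list alone, adjusted p = 0.004) and interferon response genes (Ifi27 of 7, adjusted p = 0.0103) were called higher, but adjusted p = 0.196 and 0.16 with an estimated correlation. So were oxidative phosphorylation genes, with Cox5b (0.88 ± 0.18; adjusted p = 0.00263), and ribosomal protein genes (5 of 109, adjusted p = 0.000214), each at an adjusted p = 0.428 with an estimated correlation. Astrocyte markers were lower (1 of 7 fell, 4 adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.196 with an estimated correlation), Gja1 by 2.17 on the log2 scale (-2.17 ± 0.59). Astrocyte-like cells were 180 of 1353 WT cells of the sort at 15 months and 115 of 2237 at 24 months. In all 153 of 6413 genes were called by edgeR's quasi-likelihood test, 84 higher and 69 lower. The 15-month plates are all female, so that Ddx3y was called (0 UMIs at 15 months). With female 24-month plates alone there were 72 calls, with no series term 43, and with plates summed by series, group and sex 3: Hopx (2.21), Nfkbia (-1.83) and Arrdc2 (-1.75).

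In the CD45- sort, which covers 6 to 15 months, oligodendrocyte-like cells of 5xFAD mice again held more Serpina3n (3.29 ± 0.35; 27 5xFAD and 20 WT plates; above the WT mean in 26 of 27, adjusted p = 4.56e-11), H2-D1 (1.80 ± 0.25, 25 of 27), B2m (1.50 ± 0.18, 21 of 27) and C4b (1.07 ± 0.12, 23 of 27). Bfsp2, a filament protein gene, rose by 1.45 ± 0.21 (25 of 27 above the WT mean of their own series and age). Hspa1a and Dnajb1, a heat shock protein and its co-chaperone, rose by 2.75 ± 0.66 and 1.20 ± 0.29, Pdk4 by 2.24 ± 0.55, Stmn1 by 0.94 ± 0.18, Sgk1 by 0.91 ± 0.20 (17 of 27 above the WT mean of their own series and age) and Apoe, apolipoprotein E, by 0.38 ± 0.08. Apoe was -0.11 (adjusted p = 0.791) with 6 and 10 months alone, all male. Klk6 (-0.09 ± 0.30), Vim (0.50 ± 0.36) and H2-K1 (1.00 ± 0.29, adjusted p = 0.12) did not pass. Ttr, a choroid plexus gene, rose by 0.85 ± 0.17 but did not pass with plates summed by series, group and sex (0.51, adjusted p = 0.85). Ddx3y was called because the 5xFAD plates are all male.

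Of the disease-associated oligodendrocyte list 5 of 14 members rose and none fell (9 adjusted over the list alone, median 0.50, adjusted p = 6.57e-25). The unfolded protein and integrated stress response list was higher with none of 9 passing alone (median 0.36, adjusted p = 0.000623), as were lysosome genes (0 of 17, 2 adjusted over the list alone, adjusted p = 0.00725, and adjusted p = 0.136 without the 11-month plates). Immediate early and heat shock genes were called with 1 of 10 rising (5 rose and 1 fell adjusted over the list alone, median 1.05, adjusted p = 0.00538, and adjusted p = 0.0501 with an estimated correlation). Cholesterol synthesis genes were called lower with none of 12 passing (median -0.10, adjusted p = 0.0355, and adjusted p = 0.147 with an estimated correlation). Of 4769 genes 24 were called by edgeR's quasi-likelihood test, 22 higher and 2 lower (18 and 6 with DESeq2, 21 and 5 with RLE size factors). Other settings called more falls: 20 and 19 with no series term, 18 and 7 without the 11-month plates, and 22 and 23 without the single WT plate of series 73, which leaves no series term for the 11-month 5xFAD plates. With 6 and 10 months alone, all male, 12 of the 24 were called again. At single ages there were 2 higher and 3 lower at 6 months, 14 and 4 at 8, and 38 and 14 at 10. At 11 months there were 3 and 1, and at 15 months 1 and 5. Shared with the 24-month GalC+ rises were B2m, C4b, H2-D1, Serpina3n, Ptgds and Ddx3y, 6 genes against 0.21 expected. At 8, 11 and 15 months 5xFAD plates are male and WT plates female. With plates summed by series, group and sex 6 genes were called, among them Serpina3n (3.21), H2-D1 (1.68), B2m (1.17) and C4b (0.94).

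**Figure D2:**
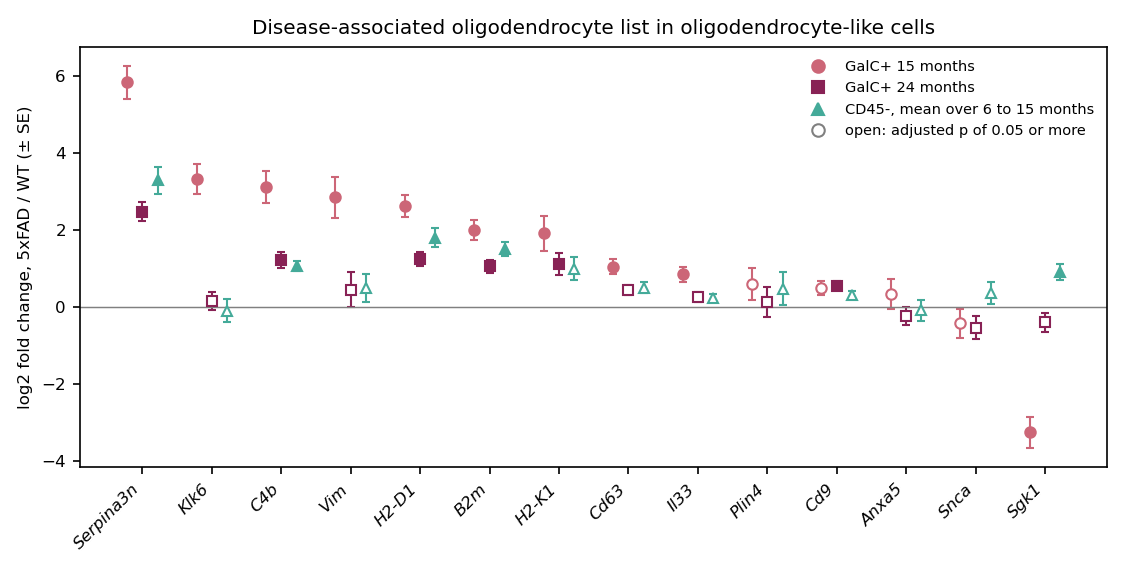
Log2 fold change of 5xFAD over WT (± SE) in oligodendrocyte-like cells for the 14 tested members of the disease-associated oligodendrocyte list, in the GalC+ sort at 15 months (circles) and 24 months (squares) and in the CD45- sort averaged over 6 to 15 months (triangles); open symbols have an adjusted p of 0.05 or more. Serpina3n, C4b, H2-D1 and B2m are filled in all 3 comparisons, and Sgk1 lies at -3.25 at 15 months and 0.91 in the CD45- sort.

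The linear trend with age of the genotype difference in CD45- oligodendrocyte-like cells was called for 2 of 4769 genes by edgeR's quasi-likelihood test (47 plates; 314 genes at an unadjusted p under 0.05, and 3 genes with DESeq2). Dbp, a clock-controlled transcription factor, fell by 0.51 ± 0.11 per month (adjusted p = 0.0219), from 0.85 ± 0.74 at 6 months to -3.70 ± 0.71 at 15 months. AC151971.8 rose by 0.66 ± 0.14 per month (adjusted p = 0.0219). No member of the disease-associated oligodendrocyte list had a called trend (0 of 14, also over the list alone, median 0.03, adjusted p = 0.892). Both calls ended with plates summed by series, group and sex, and 0 genes were called without WT 15-month replicate 1 or with no series term. Counts in other settings were 4 with at least 30 cells per plate, both genes among them, and, with neither among them, 17 with 6 and 10 months alone and 1 with plates summed.

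In astrocyte-like CD45- cells most of the calls over plates depend on 11 months. There the 3 5xFAD plates are of 1 series and the 4 WT plates of another, so that genotype and series cannot be told apart. Of 2082 genes 32 were called by edgeR's quasi-likelihood test, 11 higher and 21 lower. Without the 11-month plates 5 were called, all among the 32. Etnppl, an enzyme of phosphoethanolamine breakdown, rose by 1.52 ± 0.29 (22 against 19 plates, adjusted p = 0.000623) and Ttr by 0.81 ± 0.15, and both passed without those plates (1.95, adjusted p = 0.000626, and 0.81, 0.00377). Ttr was at 152456 CPM in choroid plexus-like cells and 696 CPM elsewhere. Those cells were a larger share of 5xFAD than of WT CD45- cells at 11 months (7.31% and 2.12%) and a smaller one at 6 months (2.89% and 5.80%). Whether their RNA reached other wells was not tested. With plates summed by series, group and sex neither Etnppl (1.34, adjusted p = 0.253) nor Ttr (0.37, adjusted p = 0.87) passed. The genes named next did not pass in the fit over plates without the 11-month plates. The summed fit also holds no 11-month set of these cells. Of the genes named next it called Myoc (adjusted p = 1.09e-06) and Clptm1 (-1.49, adjusted p = 5.85e-05) and none of the others. Myoc, myocilin (chromosome 1, 162639155 to 162649693), had 0 UMIs in the 19 WT plates and was found in 13 of 22 5xFAD plates, at least 30.5-fold higher. C4b rose by 1.00 ± 0.26, S100a10 by 0.87 ± 0.24, the glutamate receptor gene Gria1 by 0.71 ± 0.18 and Enpp2 by 0.74 ± 0.21. Clptm1 (-1.28 ± 0.33, below the WT mean of their own series and age in 15 of 19 plates), Ly6e (-1.11 ± 0.30), the sterol regulator Insig1 (-0.85 ± 0.24), Mapk8ip3 (-0.81 ± 0.22) and Slc6a11, a GABA transporter (-0.58 ± 0.16), fell, along with Hbb-bs (-1.51 ± 0.25), Hbb-bt (-1.64 ± 0.36) and the endothelial gene Ly6c1 (-1.38 ± 0.37).

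The disease-associated astrocyte list was not called in these cells: 1 of 10 rose, C4b (2 adjusted over the list alone, median 0.13, adjusted p = 0.125). Gfap (0.73 ± 0.27, adjusted p = 0.22), Vim (0.40 ± 0.17), Apoe (-0.10 ± 0.08) and Clu (-0.03 ± 0.08) did not pass. H2-D1 (0.37 ± 0.41), H2-K1 and B2m (0.13 ± 0.14) did not pass either. The unfolded protein and integrated stress response list was called higher (0 of 7, 3 adjusted over the list alone, adjusted p = 0.0288), mitochondrially encoded genes (0 of 9, adjusted p = 0.0215) and ribosomal protein genes (1 of 39 rose and 1 fell; adjusted p = 0.00765) lower, but adjusted p = 0.177, 0.303 and 0.303 with an estimated correlation. With plates summed by series, group and sex 6 genes were called, Myoc and Clptm1 among the named, and without WT 10-month replicate 2 there were 13. At single ages the counts were 0 at 6 months, 4 at 8 and 0 at 15. They were 32 at 10 months (21 higher and 11 lower) and 22 at 11 months (8 higher and 14 lower).

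Endothelial-like CD45- cells of 5xFAD mice held less of the clock-output transcription factor genes Dbp (chromosome 7, 45705088 to 45710203, -3.20 ± 0.44, 20 against 15 plates, adjusted p = 3.12e-07) and Nr1d1, or Rev-erbα (chromosome 11, 98767932 to 98775333, -1.99 ± 0.28, below the WT mean of their own series and age in 18 of 20 plates). Dbp was at 0 CPM in the 3 5xFAD plates of 8 months, so the size of its mean fold is not firm. With 20 CPM added, its mean log2 difference over 5 blocks of age and series was -1.64. At 6 months in series 66 the genotypes overlapped: 197.1, 80.9 and 181.4 CPM in 5xFAD and 161.9, 212.4 and 142.7 CPM in WT plates. They overlapped in series 68 too, at 64.3, 0, 18.4, 0 and 0 CPM in 5xFAD and 21.1, 31.9 and 55.2 CPM in WT plates. Cdkn1a, the p21 inhibitor of cell cycle kinases (chromosome 17, 29090976 to 29100727), rose by 1.41 ± 0.21 (17 of 20 plates above that mean). The heat shock genes Hspa1a (1.11 ± 0.29), Hspb1 (0.62 ± 0.11) and Hsp90ab1 (0.49 ± 0.11) rose. With plates summed by series, group and sex each had an adjusted p of 0.696. The rises shared with CD45- oligodendrocyte-like cells were Hsp90ab1, Hspa1a, Rpl34 and Ttr, 4 genes against 0.03 expected. Both classes come from the same sort and share plates, so these rises are not particular to endothelial-like cells. The mitochondrial tRNA gene mt-Tl1 (-0.99 ± 0.19, 20 of 20 plates below that mean), Copz2 (-1.19 ± 0.31), Golim4 (-0.64 ± 0.15), the amino acid transporter gene Slc7a5 (-0.57 ± 0.15) and the metallothionein gene Mt2 (-0.54 ± 0.13) fell. MHC class I genes were not higher here (0 of 12, median -0.02, adjusted p = 0.919), with H2-D1 at 0.07 ± 0.10, H2-K1 at -0.03 ± 0.11 and B2m at 0.14 ± 0.09.

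Among 15 blood-brain barrier transport and junction genes 1 fell, Slc7a5 (2 adjusted over the list alone, median 0.04, adjusted p = 0.853). With 6 and 10 months alone, all male, Slc7a5 was 0.08 (adjusted p = 0.918). With plates summed by series, group and sex it was -0.36 (adjusted p = 0.933). Cldn5 (-0.10 ± 0.10) and Slc2a1, the glucose transporter (0.20 ± 0.10), did not pass. None of 5 endothelial activation genes passed (median 0.35, adjusted p = 0.102), Vwf among them (0.35 ± 0.17). Ttr, a choroid plexus gene, rose by 1.17 ± 0.18 but did not pass with plates summed by series, group and sex (0.63, adjusted p = 0.815). Myelin genes (0 of 7, median 0.30, adjusted p = 0.0111) and oligodendrocyte markers (0 of 6, adjusted p = 0.0158) were called higher and mitochondrially encoded genes lower (0 of 9, adjusted p = 0.0394), but adjusted p = 0.468, 0.499 and 0.501 with an estimated correlation. Of 3071 genes 17 were called by edgeR's quasi-likelihood test, 6 higher and 11 lower. At single ages the counts were 2 at 6 months, 8 at 8, 56 at 10 (35 higher and 21 lower) and 11 at 15, and with 6 and 10 months alone, all male, 58. Without WT 15-month replicate 2 there were 10 and without WT 10-month replicate 2 there were 11. With plates summed by series, group and sex 4 genes were called, with Cdkn1a (1.27, adjusted p = 0.0069) and mt-Tl1 (-0.94) among them. Dbp (-1.77, adjusted p = 0.0598) and Nr1d1 (-1.33, adjusted p = 0.152) did not pass.

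**Figure D3:**
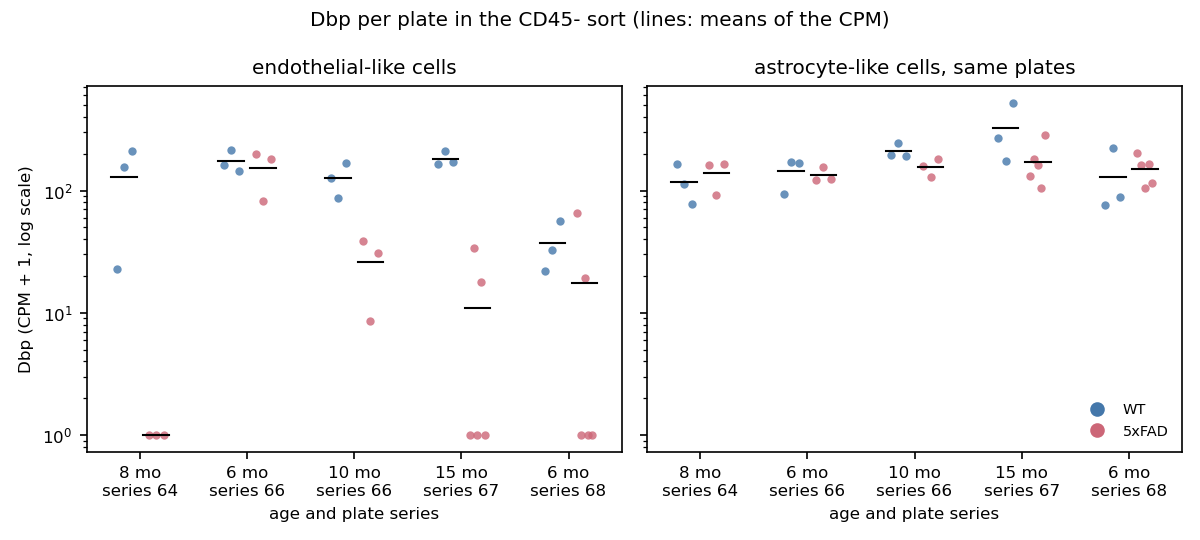
Dbp per plate (CPM + 1, log axis) in endothelial-like cells (left) and astrocyte-like cells (right) of the same CD45- plates, by age and plate series; blue points are WT and red points 5xFAD plates, and lines are the means of the CPM. The endothelial mean is lower in 5xFAD in 5 of 5 blocks of age and series, and the astrocyte mean in 3 of 5.

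Mural-like cells were few (269 cells over 16 plates), and 2 of 856 genes were called by edgeR's quasi-likelihood test: Rnf214 (-3.12 ± 0.57, 8 against 5 plates, adjusted p = 0.00242) and Tuba1c, a tubulin gene chosen after its value was seen (-2.12 ± 0.49, adjusted p below the threshold but 0.05 when rounded). Mural markers did not pass (0 of 11, median -0.22, adjusted p = 0.186), and ribosomal protein genes were called lower with none of 25 passing (adjusted p = 0.0162, and adjusted p = 0.444 with an estimated correlation). The same 2 genes were called with plates summed by series, group and sex. With at least 1000 UMIs per cell 0 genes were called, and 70 genes had an unadjusted p under 0.05.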

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

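The counts over other splits of the plates and the test of the disease-associated oligodendrocyte list in male plates were planned; the other tests of explanations given here were chosen after the result was seen.

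In 28 tests, each of 1 group of plates and 1 of 4 measures, 4 found a plate far from the others, and chance gives about 1 in 20 tests. CD45- 5xFAD 15-month replicate 6 had 118 kept cells against 196 to 231 in the others, and CD45- WT 6-month replicate 4 had 110 against 212 to 263. In CD45- WT 11-month replicate 5, the single WT plate of its series, 92.7% of kept cells were oligodendrocyte-like, against 36.5% to 51.3%. Those other WT plates are of another series. In its own series 5xFAD replicates 4 to 7 held 172 of 203, 159 of 187, 205 of 219 and 220 of 235 such cells. Replicates 1 to 3 held 56 of 226, 52 of 222 and 58 of 200. In CD45- 5xFAD 6-month replicate 8, 13.2% of oligodendrocyte-like cells held a Serpina3n UMI at 500 UMIs, against 0% to 4.44%.

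The genotype difference in GalC+ oligodendrocyte-like cells differed between 24 and 15 months for 43 genes, by a test of the difference itself. The 5xFAD plates behind it are all female at 15 months and all male at 24 months, so age and sex cannot be told apart in 5xFAD. A shift of the WT plates can give such a difference too. In WT plates Hopx and Klk6 were higher, and Sgk1 and Nfkbia lower, at 24 than at 15 months, opposite in sign to the values below. Among the named genes the difference was higher at 24 months for Arl4d (3.52), Sgk1 (2.85), Syne1 (2.35), Nfkbia (2.19), Malat1 (1.57), Rsrp1 (1.41), Amer2 (1.25) and Phactr3 (1.19). It was lower for Tubb3 (-3.38), Serpina3n (-3.36), Klk6 (-3.17), Fgfrl1 (-2.59), Tspan9 (-2.43), Hopx (-2.31), Aldh1l2 (-2.19), C4b (-1.90), Map3k11 (-1.75), Enpp6 (-1.45), H2-D1 (-1.38), Olfm1 (-1.36), Trf (-0.75) and Ctsb (-0.73). In CD45- oligodendrocyte-like cells the difference changed with age for 2 genes, AC151971.8 (0.66 per month) and Dbp (-0.51 per month).

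A cluster of 493 cells led by the myeloid genes Lyz2, Ccl4 and Ctss entered no comparison and was found mostly in 1 group. It held 464 of 3182 GalC+ 5xFAD cells at 24 months (14.6%, 95% Wilson interval 13.4 to 15.9), and 0 of 2237 WT cells of that age. Of its cells 463 came from series 91, which holds no WT plate, and 3 plates held over 10%: 159 of 174 cells in replicate 4, 136 of 259 in replicate 5 and 156 of 315 in replicate 7. Genotype and series cannot be told apart for these cells.

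Disease-associated oligodendrocyte genes were higher in 5xFAD oligodendrocyte-like cells in both sorts. Sex as the whole cause is argued against by the CD45- plates of males alone, where the list median was 0.49. RNA of astrocytes in the same wells is argued against at 15 months by the astrocyte markers, whose median was -0.60 while the list rose. At 10 months it stays open, since the astrocyte markers rose as well (median 1.34). A strain variant that changes H2-D1 in every cell is argued against by H2-D1 in endothelial-like cells (0.07 ± 0.10, against 1.80 ± 0.25 in oligodendrocyte-like cells). Plates that share an animal, and counting of reads shared by near-identical genes, stay open. A biological effect of the transgenes may underlie the rise and also stays open.

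Sgk1 and 12 other genes were lower in 5xFAD GalC+ oligodendrocyte-like cells at both 10 and 15 months. A genotype effect common to all ages and sorts is argued against, since the median of the 13 genes was higher in 5xFAD in 5 of 9 comparisons within a series and age (range -1.19 to 0.91). Differences between sets of plates could not be excluded: sets of 1 group and sex differed by up to 0.68 in the same median, against a genotype difference of -1.11 at 15 months. With 7 such pairs of sets, a state of the animals or of the preparation that differs between sets and a genotype effect at those ages cannot be told apart.

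Dbp and Nr1d1 were lower in 5xFAD endothelial-like cells. Time of day or handling shared by all cells of a plate is argued against as the whole cause by the astrocyte-like cells of the same plates: the genotype difference of log2 Dbp was lower in endothelial-like cells by -1.50 (permutation p = 4e-05 within blocks of age and series). A part of the fall at 15 months stays open to it, since Dbp at that age was also lower in oligodendrocyte-like cells (-3.70 ± 0.71) and its mean in 5xFAD astrocyte-like cells was 172 CPM against 321 CPM in WT. The same holds for Nr1d1 at 8 months, at 113.2, 90.1 and 162.7 CPM in 5xFAD and 258.5, 214.2 and 345.1 CPM in WT astrocyte-like cells. Over the 5 blocks Nr1d1 in astrocyte-like cells was lower in 5xFAD in 2, with a mean log2 difference of 0.01 (permutation p = 0.958). Sex as the whole cause is argued against by the male plates, where the smaller of both falls was -1.36 (Dbp, adjusted p = 0.0173). Among those plates the genotypes overlapped at 6 months for both genes. They were apart at 10 months, in 3 plates of each genotype of series 66. Time of day that acts on endothelial cells alone stays open, as no times are given in the sources used here, and so do plates that share an animal and a biological effect of the transgenes.

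Other splits of the same plates argue against a chance allotment of single plates for the 24-month comparison, where 1 of 100 splits (the real one) called as many as 97 genes and the highest other called 11. The same holds for WT age (1 of 100, 153 genes, highest other 55), CD45- oligodendrocyte-like cells (1 of 100, 24 genes, highest other 14) and endothelial-like cells (1 of 100, 17 genes, highest other 10). In astrocyte-like cells 1 of 100 splits called as many as 32 and the highest other called 13. Those counts cannot be set side by side, since the 32 include a difference between series at 11 months that regrouped labels can move into a series term. At 15 months 2 of 84 splits called as many as 143, and the highest other, 163, exchanged the genotypes of the series-140 plates of that age. For genotype by age 4 of 100 splits called as many as 43, and the highest other called 102 after the same exchange together with exchanges among the 24-month plates. Chance was not excluded for the trend with age (9 of 100; 2; 5) or for mural-like cells (32 of 100; 2; 15). The splits treat plates as independent and break up the sets of 1 series and sex that the real genotypes follow. They therefore cannot exclude a difference between sets of plates or between animals.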

How the results depend on the processing

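The alternatives by sex, by summed plates, without series 91, without the 11-month plates and with the unnamed cluster added were chosen after the results were seen; the others were planned. Over 207 called values of named genes, 2884 of 3783 alternative values kept their direction and passed, 889 kept their direction and did not pass, and 10 reversed. Except where stated, the cause was not tested.

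With plates summed by series, group and sex the counts fell from 97 to 9 at 24 months, 143 to 20 at 15 months, 407 to 80 at 10 months, 43 to 1 for genotype by age, 153 to 3 for WT age, 24 to 6 in CD45- oligodendrocyte-like cells, 2 to 1 for their trend, 32 to 6 in astrocyte-like and 17 to 4 in endothelial-like cells; this setting has fewer replicates. With no series term the counts were 147 at 24 months (47 of the 97 called again), 180 at 10 months, 43 for WT age, 39 in CD45- oligodendrocyte-like cells, 0 for their trend (edgeR), 18 in astrocyte-like and 1 in mural-like cells. With all kept cells of the GalC+ sort they were 155 (64 of the 97 called again), 266, 907, 26 and 312 for 24 months, 15 months, 10 months, genotype by age and WT age. With females alone they were 654 at 10 months and 72 for WT age. With at least 30 cells per plate they were 12 in CD45- oligodendrocyte-like cells, 4 for their trend and 16 in astrocyte-like cells, and no value could be had in mural-like cells. With 6 and 10 months alone, all male, they were 17 for the trend, 15 in astrocyte-like and 58 in endothelial-like cells. Without the 11-month plates they were 5 in astrocyte-like cells and 1 for the trend. With at least 1000 UMIs per cell they were 16 in astrocyte-like and 0 in mural-like cells, and in mural-like cells DESeq2 and no filter on low counts gave 1 each. Of 156 list tests 51 were called, and 24 with an estimated correlation.

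Leaving out 1 plate at a time gave 83 to 107 calls at 15 months (83 without 5xFAD replicate 3), 63 to 172 at 10 months (63 without WT replicate 1, 172 without WT replicate 2) and 22 to 28 for genotype by age (22, 28 and 26 without 5xFAD 15-month replicates 1, 2 and 3). In CD45- oligodendrocyte-like cells it gave 20 to 45 (45 without WT 11-month replicate 5), and for their trend 0 to 3 (0 without WT 15-month replicate 1, 1 without WT 15-month replicate 3). In endothelial-like cells it gave 10 to 19 (10 without WT 15-month replicate 2, 11 without WT 10-month replicate 2). In astrocyte-like cells it gave 13 to 32: 13 without WT 10-month replicate 2, 14 without 5xFAD 10-month replicate 1, 20 without 5xFAD 15-month replicate 2, 5xFAD 8-month replicate 1 or 2, or WT 11-month replicate 1 or 2, and 21 without 5xFAD 10-month replicate 2, 5xFAD 11-month replicate 2, or WT 8-month replicate 2 or 3. In mural-like cells it gave 1 to 2, with 1 in 10 of 12 fits: without 5xFAD 10-month replicate 1, 2 or 3, 5xFAD 6-month replicate 2, 3, 5 or 8, or WT 6-month replicate 2, 5 or 6.

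Reversed values at 24 months were Hba-a1 (0.03 with at least 1000 UMIs per cell), AC158232.1 (0.04 with no series term), Hbb-bs (0.61) and Txnip (0.39) in males alone, and Ddx3y (-0.25 with a sex term, -0.27 in males alone). For WT age Fgfrl1 was -0.12 with all kept cells, and Ddx3y 0 in females alone, which lack the gene. With 6 and 10 months alone Apoe was -0.11 in CD45- oligodendrocyte-like and Slc7a5 0.08 in endothelial-like cells. The ribosomal protein list for WT age (adjusted p = 0.973 with no series term) and the cholesterol synthesis list in CD45- oligodendrocyte-like cells (adjusted p = 0.572 with 6 and 10 months alone) also reversed. The share of cells with a Serpina3n UMI passed under its alternatives, with differences of 6.79 to 12.5 percentage points. The plate as replicate, planned as an alternative to the animal, is the setting reported, since no animals are named, and no paired analysis was possible, since replicate numbers follow the order of deposit.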

Other observations

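The test given here was chosen after the result was seen. Within series 87, the GalC+ 5xFAD plates at 10 months, 15.6% ± 1.99 of oligodendrocyte-like cells held a Serpina3n UMI in female plates (SD, n = 3) and 6.06% ± 2.21 in male plates (n = 6), at 500 UMIs per cell. The difference was 9.55 percentage points (exact two-sided permutation p = 0.0119 over 84 permutations), and 3 of 3 female plates lay above the highest male plate. Sex may be related to this share in 5xFAD mice. Plates of 1 sex can come from 1 animal, so that sex and animal are not separated.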
